A study of Mus musculus with 2 samples.

How the data were processed

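B16 melanoma cells were kept in medium with 5% fetal bovine serum, preincubated for 24 h, transfected with a Fam222B siRNA or a control siRNA using a lipid reagent, and harvested 48 h later, per the labels' protocols. Total RNA was labelled with Cy5 and hybridised to Toray 3D-Gene miRNA arrays, which have 1 colour. Each group, taken from the treatment given in the labels, had 1 array.

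The deposited scanner files give the median intensity of each spot at 635 nm, per the file headers, with no background subtracted. The scanner and the software version are not given in the sources used here. Each array had 3200 spots in 32 blocks: 1900 miRNA probes (12 of which name several miRNAs), 896 blank spots, 174 spots named No Probe and 230 other control spots. The authors' table of processed intensity values for the same arrays was set against the scanner values: each of its columns is a straight line in the spot median, with a background equal to the trimmed mean of the array's blank spots (70.2 units for control-siRNA, 69.8 for Fam222B-siRNA) and factors of 3.40 and 3.69. Its medians were 25 over 1220 listed probes and 34.6 over 961. The scale is linear, not centred per miRNA, and the scaling sets the median ratio over shared probes to 1.

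The rules for samples, tests, lists and named miRNAs were fixed beforehand. A miRNA was called detected where its spot exceeded the mean plus 2 SD of the array's blank spots, after 5% of these were left out at each end (thresholds of 72.6 and 72.5 units). Spots with an NG flag were left out, which removed miR-679-3p from the control-siRNA array and miR-6382 from the Fam222B-siRNA array. Background was corrected with normexp in limma 3.58.1 (R 4.3.3) with an offset of 50, values were quantile normalized over the miRNA probes, and differences are log2 of Fam222B-siRNA over control-siRNA. A log2 difference on this scale understates the change of dim miRNAs. Net signal is the spot minus the trimmed mean of the blank spots. For a miRNA detected on 1 array only, the ratio is a bound: the bright value against the higher of the lowest detected signal and the miRNA's own value on the other array.

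The design placed first a correction by local background, and the blank spots only where no background column was at hand. The files hold a column headed BG_Median, but it followed the brightness of its own spot: Spearman's rho was 0.791 over 97 miRNA spots of at least 100 net units on the control-siRNA array and 0.897 over 96 on the Fam222B-siRNA array, and it was at or above the spot for 194 and 137 detected miRNAs. The correction without that column was therefore used as the main setting. This choice was made after the files and the spread of the authors' values had been seen, and before counts were computed under any setting. The correction with that column is given as an alternative.

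With 1 array per group there was no test, p-value or standard error between groups, and the number of arrays limits the precision. Spot SDs were built from 5 bright control probes printed 8 times on each array (pooled CV 4.67% and 4.78%) and the SD of the blank spots (1.54 and 1.66 units). They cover spot-to-spot spread within an array only. Differences were counted at 2-fold, and 1.5-fold was an alternative. For each of 25 lists fixed beforehand and 3 classes by miRBase number, the median difference was taken over members detected on both arrays, and with at least 3 such members its percentile among 10000 random lists, matched on signal in 10 bins, was computed as a description of these arrays. Correlations between the products of a hairpin were set against shuffled pairs. Named miRNAs are the 10 highest and 10 lowest differences at or above the median signal of those detected on both arrays, the 5 highest and 5 lowest among all detected on both arrays, the 3 brightest detected on each array alone, the 5 brightest on both, and from each list its highest and lowest member with further examples by signal. miR-211-3p, miR-34c-5p and miR-143-5p fall outside this rule and were named after their values were seen. Names are those of the array's design, and no coordinates are given because the files name no genome build.

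The steps were tested on simulated arrays with known changes. Under the main setting 97.2% of 71 simulated 2-fold changes had the right sign, 0% of them reached 2-fold, and 0 of 853 unchanged miRNAs passed 2-fold. With the blank signal subtracted and equal medians 40.8% of the 2-fold and 98.5% of the 4-fold changes (68 miRNAs) passed 2-fold, as did 17 of 853 unchanged ones. These shares leave out changed miRNAs that were not detected on both simulated arrays. Both simulated arrays had the control-siRNA array's background and no block effect. Their background SD was the trimmed one of its blank spots (1.17 units), below the SDs of 1.54 and 1.66 used for the spot SDs.

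Alternatives chosen before the data were examined were an offset of 16, subtraction of the blank mean with no offset, scaling to equal medians or 75th percentiles, cyclic loess, no normalization, all miRNA probes, only miRNAs at or above the median signal, detection at 5 SD, the authors' table and the lower fold threshold. A further 7 were added after seeing the data: the BG_Median column, the No Probe spots as background, blank subtraction with equal medians, scaling to the 2 spike controls, keeping NG spots, leaving out blocks 17, 18, 25 and 26, and that step together with blank subtraction and equal medians. For detection alone, thresholds with only the mean or only the SD taken from the No Probe spots were also added then. The blocks were picked from the data as those with at least 2 dim miRNA spots (under 80 units on the control-siRNA array) that gained over 5 units. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the counts and figures.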

Results

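miRNA levels were measured in B16 cells, a pigmented mouse melanoma line, after transfection with a small interfering RNA (siRNA) against Fam222B or with a control siRNA. RNA was taken 48 h after the siRNA was given. There was 1 array per group (n = 1), so no value below has a replicate error and no test between the groups was possible. Each array carried 1900 miRNA probes with 1 spot each. In control-siRNA cells 1219 probes (64.2%) gave signal above the array's blank spots, and in Fam222B-siRNA cells 958 probes (50.4%) did. Most of this signal was weak: net of the blank spots, 746 of the 1219 and 500 of the 958 lay under 10 intensity units. The median net signals of the detected miRNAs were 7.36 and 9.39 units. Signal was concentrated in a few miRNAs, and the brightest pair on each array held 52.3% of all net signal in control-siRNA cells and 51.9% in Fam222B-siRNA cells. Over the 910 miRNAs detected on both arrays, log2 net signals correlated with Pearson's r = 0.974 and Spearman's rho = 0.918, across miRNAs, which are not independent replicates. The Fam222B transcript is an mRNA that these probes do not measure, so the knockdown itself was not analysed here.

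The comparison asked which miRNAs differ in level between B16 cells given the Fam222B siRNA and cells given the control siRNA. Among miRNAs of strong signal, miR-211-5p, a melanocyte miRNA encoded in an intron of Trpm1, was higher in Fam222B-siRNA cells, at 326 net units against 264 (log2 difference 0.28, within-array spot SD 0.083). It was printed in block 25, where many dim spots also gained signal, its partner arm miR-211-3p elsewhere differed by -0.087, and with the files' own background column its difference was -0.69. miR-143-3p, a miRNA abundant in smooth muscle and fibroblasts, was lower, at 112 against 140 net units (log2 difference -0.22, spot SD 0.071), as was miR-6968-5p, at 271 against 337 (-0.29, spot SD 0.083), but on the blank-subtracted scale with equal medians they were at -0.20 and -0.19, within 2 spot SD. The other arm of the miR-143 hairpin, miR-143-5p, differed in the other direction on the main scale. The let-7, miR-17-92, miR-23, miR-24, miR-27, miR-29 and miR-30 groups, which gave much of the signal of well known miRNAs, had medians between 0 and 0.039, and between 0.10 and 0.16 on that blank-subtracted scale. Over the 96 miRNAs with at least 100 net units on both arrays the median on the latter scale was 0.14.

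The 10 highest differences among miRNAs at or above the median signal ran from 0.26 to 0.37 on the main log2 scale. miR-1971 had the highest, at 26.1 net units in Fam222B-siRNA cells against 8.94 in control-siRNA cells (0.37). It was followed by miR-6394 at 39.0 against 20.6 units (0.34), miR-7053-3p at 24.4 against 9.12 units (0.33) and miR-7677-5p at 17.6 against 4.11 units (0.33). miR-505-5p was higher by 0.30, miR-7665-5p by 0.29, miR-6368, miR-211-5p and miR-547-5p by 0.28 each, and miR-6919-3p by 0.26. All 10 were printed in 4 of the 32 blocks of the array, numbers 17, 18, 25 and 26. These blocks were picked after seeing the data, as those with at least 2 dim miRNA spots (under 80 units on the control array) that gained over 5 units on the Fam222B-siRNA array. By that choice they held 30 of the 32 such spots and 172 of the 1421 dim spots. miR-1971, miR-7053-3p, miR-7677-5p, miR-6368, miR-547-5p and miR-6919-3p were themselves such spots. Their place in these blocks therefore follows in part from the choice. The other arm of the miR-211 hairpin, miR-211-3p, was printed outside these blocks and differed by -0.087 (spot SD 0.064), at 70.4 net units against 83.4.

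The 10 lowest differences ran from -0.29 to -0.17, and 9 of these miRNAs were printed outside the 4 blocks. After miR-6968-5p came miR-6955-5p at 577 net units against 663 (-0.25), miR-34c-3p at 4.96 against 16.1 (-0.23) and miR-143-3p (-0.22). miR-34c-3p, from a hairpin whose transcription p53 activates, was printed inside the blocks, and its partner arm miR-34c-5p gave 13.4 net units on each array. miR-3102-5p, miR-6916-5p and miR-7000-3p were each lower, with differences of -0.20. miR-6912-5p, miR-5122 and miR-8113 followed with -0.18, -0.18 and -0.17. On the blank-subtracted scale with equal medians, chosen after seeing the data, miR-34c-3p (-1.57), miR-6916-5p (-0.75), miR-8113 (-0.42) and miR-5122 (-0.40) stayed lower by more than 2 spot SD. The other 6 did not, with miR-6968-5p at -0.19, miR-6955-5p at -0.077 and miR-143-3p at -0.20 (spot SD 0.097, 0.097 and 0.100), while all 10 of the highest stayed past it.

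**Figure D1:**
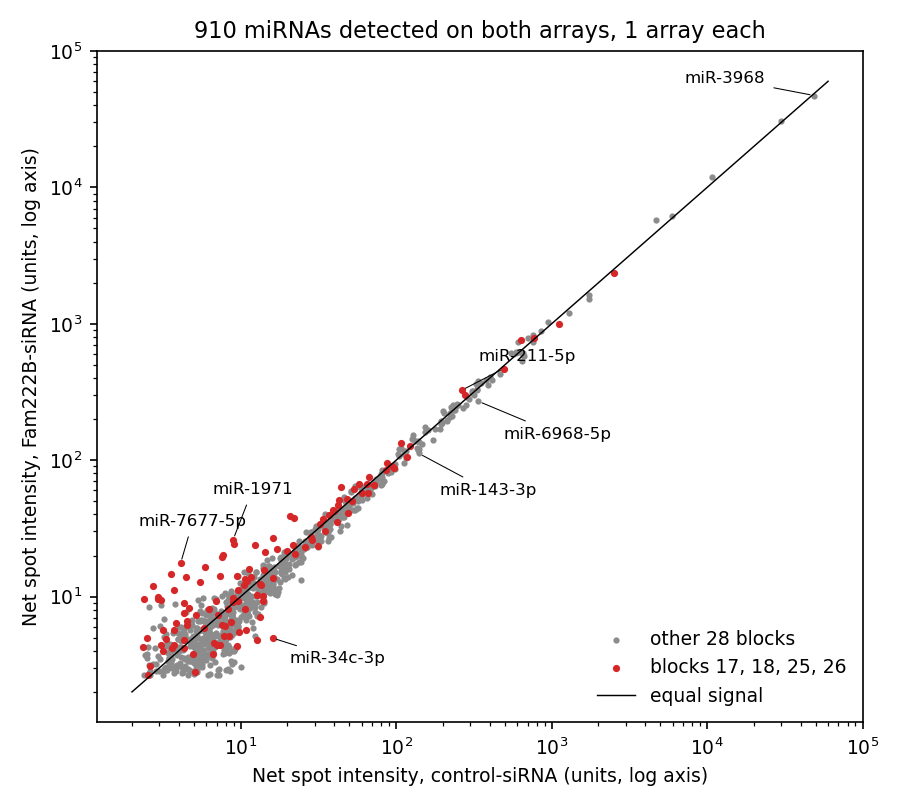
Net spot intensity (spot minus the mean of the array's blank spots, log axes) of the 910 miRNAs detected on both arrays, control-siRNA on the x axis and Fam222B-siRNA on the y axis, with 1 array each and no error bars. Points lie close to the line of equal signal at high intensity (r = 0.974 over all), and points far above the line among dim miRNAs, such as miR-1971, are mostly red, the colour of blocks 17, 18, 25 and 26. These blocks were picked for dim spots that gained, miR-1971 among them.

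No miRNA of the 910 differed by 2-fold or more in either direction on this scale, where differences ran from -0.29 to 0.37. The scale carries an offset of 50 units, which damps the differences of dim spots. In simulated arrays a true 2-fold change reached 2-fold on it for 0% of 71 miRNAs and a true 4-fold change for 16.2% of 68. These are the changed miRNAs still detected on both simulated arrays. With the blank signal subtracted, no offset and equal medians, a setting chosen after seeing the data, 27 miRNAs were at least 2-fold higher and 22 at least 2-fold lower. In the simulated arrays 17 of 853 unchanged miRNAs passed 2-fold under this setting, at a background SD below those used for the spot SDs. Noise alone thus places some miRNAs past 2-fold there, and these are not counts of changed miRNAs. Without the 4 blocks the counts of 27 and 22 became 6 and 19. The blocks were picked for dim spots that gained, so leaving them out lowers the first count in part by construction. The authors' table, which lists values for 913 miRNAs on both arrays, gave 26 and 22. It has the blank background and the equal medians of that setting, so its counts are not separate support. On the blank-subtracted scale miR-7677-5p was 4.66-fold, miR-1971 3.18-fold and miR-6394 2.05-fold higher in Fam222B-siRNA cells, while miR-34c-3p was 2.97-fold lower. miR-211-5p was 1.34-fold higher there, and miR-143-3p was 1.15-fold lower.

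Set against the spread between repeated spots within an array, 49 miRNAs were higher and 29 lower by more than 2 spot SD on the main scale. The other 91.4% of the 910 lay within 2 spot SD. Spot noise alone also places some miRNAs past 2 spot SD, so these are not counts of changed miRNAs. Inside the 4 blocks 34 of 123 miRNAs were higher and 3 lower by this measure, and outside them 15 of 787 were higher and 26 lower. Since the blocks were picked for dim spots that gained, part of this split follows from the choice. On the blank-subtracted scale with equal medians 73 were higher and 14 lower by more than 2 spot SD, 37 and 3 of them inside the blocks and 36 and 11 outside, so the balance outside the blocks turned with the scale. The spot SD holds no difference between cultures, RNA preparations, labellings or hybridisations, so these counts compare the 2 arrays and not the 2 treatments. Of 26 named miRNAs past 2 spot SD, 11 changed sign with the files' own background column, miR-211-5p (-0.69) and miR-6968-5p (0.23) among them, and 4 with scaling to the spike controls, which moved the median of all miRNAs by 0.15. That column followed the brightness of its own spot. With it the differences of the 96 miRNAs with at least 100 net units had an SD of 0.81, against 0.11 on the main scale.

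Among miRNAs of the melanocyte lineage and pigmentation, 14 of 21 were detected on both arrays, 4 with higher and 10 with lower values in Fam222B-siRNA cells, and the median difference was -0.025. This lay at the 16.7th percentile of 10000 random lists of the same size and signal. Without the 4 blocks it was -0.028 (20.4th percentile) on the main scale, and with the No Probe background -0.083 (10.9th percentile). Blank subtraction with equal medians gave -0.11 (3.65th percentile), and -0.21 (3.03rd percentile, 9 members) without the 4 blocks. The 4 higher members were miR-211-5p, miR-25-3p (0.14), miR-27a-3p and miR-143-5p (0.12 each). miR-25-3p and miR-211-5p were printed in the 4 blocks. miR-218-5p had the lowest value, at 5.15 net units against 12.4 (-0.15). The melanoma progression list had 14 of 22 members detected on both arrays, 10 higher and 3 lower, with a median of 0.032 at the 94.8th percentile, and of 0.019 (88.8th percentile, 10 members) without the 4 blocks. Blank subtraction with equal medians gave 0.16 (89.7th percentile), and 0.15 (85.7th percentile) without the 4 blocks. In it miR-31-5p was at 625 against 590 net units (0.12), miR-30b-5p at 590 against 656 (-0.11), and miR-21a-5p, widely raised in tumours, at 319 against 313 (0). The median of this list was negative only with the files' own background column, and with the No Probe background it was 0.14 (97.9th percentile, 17 members).

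The p53-responsive list was the only one whose median lay outside the central 95% of the random lists on the main scale, among the 21 lists and number classes with at least 3 detected members. Chance alone would place about 1 of 21 lists there. Its median was -0.063, at the 2.23rd percentile, with 3 of 9 detected members higher and 6 lower. miR-143-3p (-0.22) and miR-145a-5p (-0.12), products of 1 cluster, were the members lower by more than 2 spot SD, which they were not on the blank-subtracted scale with equal medians (-0.20 and -0.21). The other arm of the miR-143 hairpin, miR-143-5p, which is not in this list, was higher by 0.12 on the main scale. miR-16-5p was at 741 against 760 net units (-0.13), and miR-34a-5p, the best known p53 target of the list, at 127 against 123 (0.045). With the blank signal subtracted and equal medians the median of the list was 0.023, at the 19.8th percentile, and with the authors' values, on nearly the same scale, it was 0.020. With scaling to the spike controls it was 0.12, where the median of all miRNAs was 0.15. Without the 4 blocks, 8 members had a median of -0.080 (0.49th percentile) on the main scale and -0.079 (6.03rd percentile) with the blank signal subtracted and equal medians.

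Of the families expressed in most cells, let-7 had 6 higher and 3 lower of 10 members and a median of 0.039, which was negative only with the files' own background column. let-7k was higher by 0.14 and let-7a-5p by 0.12, let-7g-5p had a difference of -0.15, and let-7c-5p was at 886 against 857 net units (0). The miR-17-92 and related clusters, known for promoting proliferation, had 6 higher and 5 lower of 13 and a median of 0, with miR-25-3p at 0.14, miR-19a-3p at -0.089 and miR-17-5p at 0. The miR-30 family (2 higher and 2 lower of 5) and the miR-23, miR-27 and miR-24 clusters (2 higher and 1 lower of 5) also had medians of 0, with miR-30b-5p at -0.11 and miR-27a-3p at 0.12 as their widest members. The miR-130, miR-301, miR-148 and miR-152 families had 2 higher and 2 lower of 6, a median of 0 and miR-301a-3p at 0.074. Quantile normalization gives a difference of 0 to any miRNA that holds its rank, so these zeros do not show equal levels. On the blank-subtracted scale with equal medians the medians were 0.16 for let-7, 0.10 for the miR-17-92, 0.13 for the miR-30, 0.15 for the miR-23, miR-27 and miR-24 and 0.036 for the miR-130, miR-301, miR-148 and miR-152 group. In that order they lay at the 77.0th, 61.4th, 39.8th, 64.4th and 32.9th percentiles of random lists matched on signal. All 96 miRNAs with at least 100 net units on both arrays had a median of 0.14 on that scale, so bright miRNAs in general lay above 0 there. With the files' own background column the median of the miR-23, miR-27 and miR-24 clusters was 0.50. The miR-29 family had 2 higher and 1 lower of 3, with miR-29b-3p at 0.085 and a median of 0.014 that was negative only with the files' own background column. The miR-15 and miR-16 family had 2 higher and 4 lower of 6 (median -0.027), and the miR-99, miR-100, miR-125 and miR-10 family had 3 higher and 4 lower of 7 (median -0.027), with miR-10a-5p at -0.11. The miR-181 family had 2 higher and 2 lower of 4 (median 0.0041). The medians of these last 3 lists changed sign on the blank-subtracted scale with equal medians, and without the 4 blocks they were -0.0081, -0.14 and -0.12 on that scale.

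Among the imprinted Dlk1-Dio3 clusters, 12 of 46 miRNAs were detected on both arrays, 3 higher and 9 lower (median -0.0077, 22.3rd percentile). The median was -0.12 (4.84th percentile) with the blank signal subtracted and equal medians, and -0.11 (36.5th percentile, 20 members) with the No Probe background. miR-487b-3p was at 143 against 127 net units (0.16), while miR-770-3p had a difference of -0.057, and 12 further members were detected in control-siRNA cells alone. The Sfmbt2 intron cluster had 6 higher and 2 lower of 8 (median 0.027), with miR-466h-5p at 0.069. The miR-290-295 cluster, a group of embryonic stem cells, had 1 higher and 3 lower of 4 (median -0.029), with miR-290a-5p at -0.11. On the blank-subtracted scale with equal medians its median was -0.35 (4.28th percentile) and that of the Sfmbt2 intron cluster 0.19 (91.7th percentile). The Dlk1-Dio3 median turned positive and the Sfmbt2 median negative with the files' own background column. The Sfmbt2 median was also negative with detection at 5 SD and among miRNAs at or above the median signal. Of miRNAs that respond to interferon and inflammation, 1 was higher and 4 were lower of 6 (median -0.019), with miR-9-5p at 0.11 and miR-132-3p at -0.086. With scaling to the spike controls the medians of the melanocyte, interferon, Dlk1-Dio3 and miR-290-295 lists were positive but below the median of all miRNAs, and with equal 75th percentiles the same held for the first 3. The hypoxia-responsive miR-210-3p was at 224 against 221 net units (0), and miR-210-5p at 23.5 against 31.3 (-0.10). miR-221-3p, printed in block 25, was at 43.5 against 39.2 net units (0.11) and was the only member of the miR-221 and miR-222 list detected on both arrays. With the No Probe background 3 members were detected, with a median of -0.68 (2.21st percentile).

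Markers of other cell types were mostly weak. Of the fibroblast and smooth muscle list 2 were higher and 2 lower of 4 (median -0.040), with miR-143-3p and miR-145a-5p lower and miR-199a-5p at 0.075. Its median was 0.052 with the blank signal subtracted and equal medians. Without the 4 blocks, which removed miR-199a-5p, the other 3 had a median of -0.12 (0.88th percentile) on the main scale and -0.20 (1.36th percentile) with the blank signal subtracted, and miR-143-3p and miR-145a-5p are also in the p53-responsive list. The neuronal list had 3 higher and 2 lower of 5 (median 0.048, 94.0th percentile, and 0.016 without the 4 blocks), with miR-9-5p at 143 against 129 net units and miR-138-5p at -0.077. Its median was 0.26 (96.1st percentile) with blank subtraction and equal medians, and 0.074 (63.4th percentile) there without the 4 blocks. With the No Probe background it was 0.030 (67.8th percentile). miR-451a of blood cells gave 12.2 against 13.6 net units. The endothelial miR-126a-3p gave 12.3 net units in Fam222B-siRNA cells (0.018), the muscle miRNA miR-133b-3p 4.28 against 8.10 and the epithelial miR-200b-3p 3.71 against 2.44. The hepatocyte miRNA miR-122-5p was not above the blank spots on either array. The classes of low, intermediate and high miRBase number had medians of -0.00086, -0.012 and 0.

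**Figure D2:**
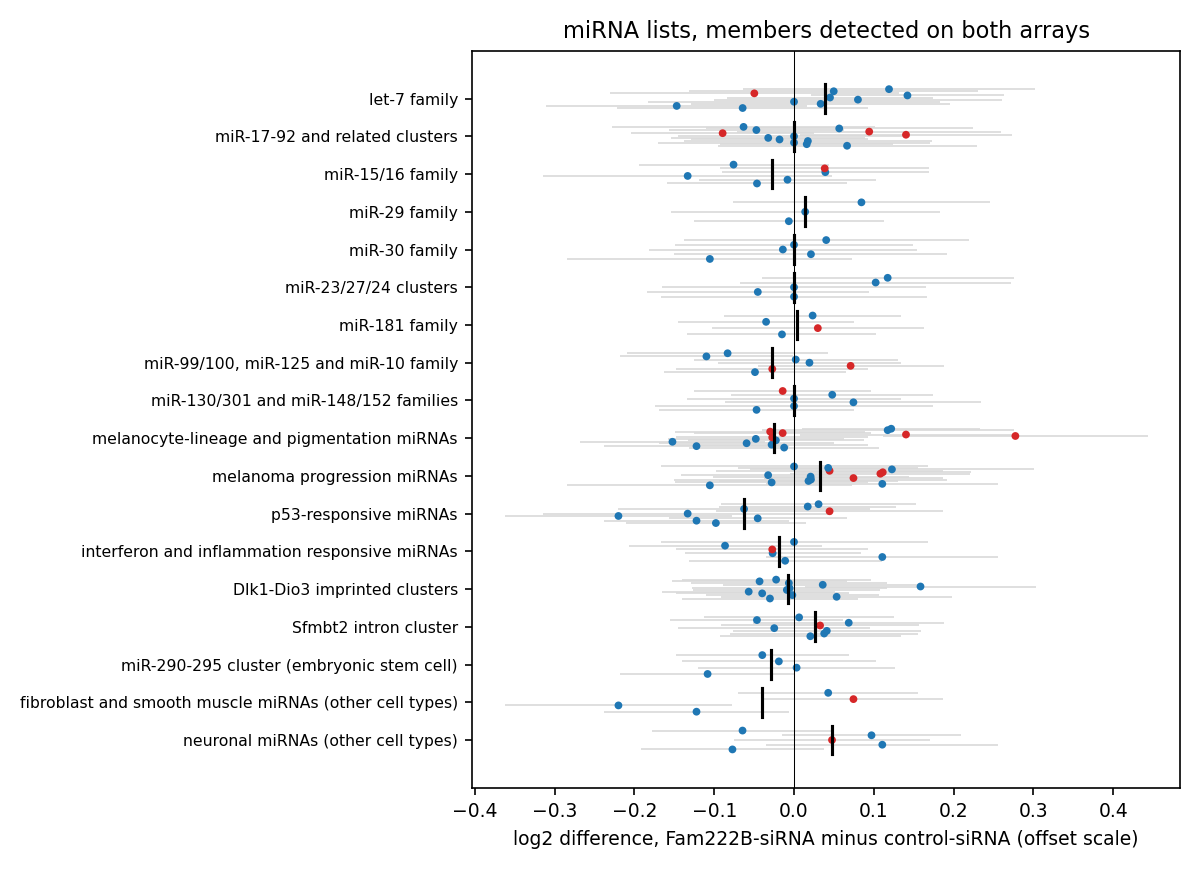
Log2 differences (Fam222B-siRNA minus control-siRNA, main scale with offset) of the members of each list with at least 3 miRNAs detected on both arrays, 1 array per group. Points are miRNAs, red where printed in blocks 17, 18, 25 or 26 and blue elsewhere, grey bars are 2 within-array spot SDs on each side and black ticks are list medians; the p53-responsive list has the lowest median (-0.063), which is 0.023 with the blank signal subtracted and equal medians and -0.079 there without the 4 blocks.

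The 5 brightest miRNAs, miR-3968, miR-5100, miR-6366, miR-6412 and miR-3963, held the same ranks on both arrays, so that quantile normalization set each difference to 0. On the blank-subtracted scale with equal medians miR-3968 was 1.05-fold, miR-5100 1.12-fold and miR-3963 1.33-fold higher in Fam222B-siRNA cells. Over the 96 miRNAs with at least 100 net units on both arrays the median fold was 1.10 on that scale.

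Detection differed in 1 direction more than the other: 309 miRNAs were above the blank spots in control-siRNA cells alone and 48 in Fam222B-siRNA cells alone. The brightest of the first kind were miR-672-3p, miR-669f-5p and miR-6902-3p, at least 1.09-fold, 1.08-fold and 1.07-fold higher in control-siRNA cells (2.97-fold, 2.86-fold and 2.76-fold at least with the blank signal subtracted). The brightest of the second kind were miR-196b-3p, miR-7677-3p and miR-7673-3p, at least 1.43-fold, 1.24-fold and 1.23-fold higher in Fam222B-siRNA cells, and all 3 were printed in the 4 blocks. With the blank signal subtracted, where no offset damps dim spots, these bounds were 11.5-fold, 6.67-fold and 6.51-fold. miR-196b-3p, miR-7677-3p and miR-7673-3p were themselves spots of the kind by which the blocks were picked, so their place there follows in part from that choice. With the spots named No Probe as the background in place of the blank spots, an alternative chosen after seeing the data, the counts were 170 and 104. They were 161 and 43 with detection at 5 SD, and 291 and 22 without the 4 blocks.

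The 5p and 3p products of a hairpin come from 1 precursor. Over 220 hairpins with both products detected on both arrays, their log2 differences correlated with Pearson's r = 0.160 and Spearman's rho = 0.198, and 55.5% had the same sign. These are correlations across miRNAs, which are not independent replicates. Shuffled pairs gave a 95% range of r from -0.131 to 0.131. Among miRNAs at or above the median signal r was 0.073, with detection at 5 SD it was 0.069, with the No Probe background it was 0.247, and with the files' own background column it was -0.061. Without the 4 blocks r was 0.081 over 178 hairpins, against a shuffled range from -0.147 to 0.148. After blank subtraction with equal medians r was 0.192, and without the 4 blocks it was 0.140, against a shuffled range from -0.149 to 0.149.

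**Figure D3:**
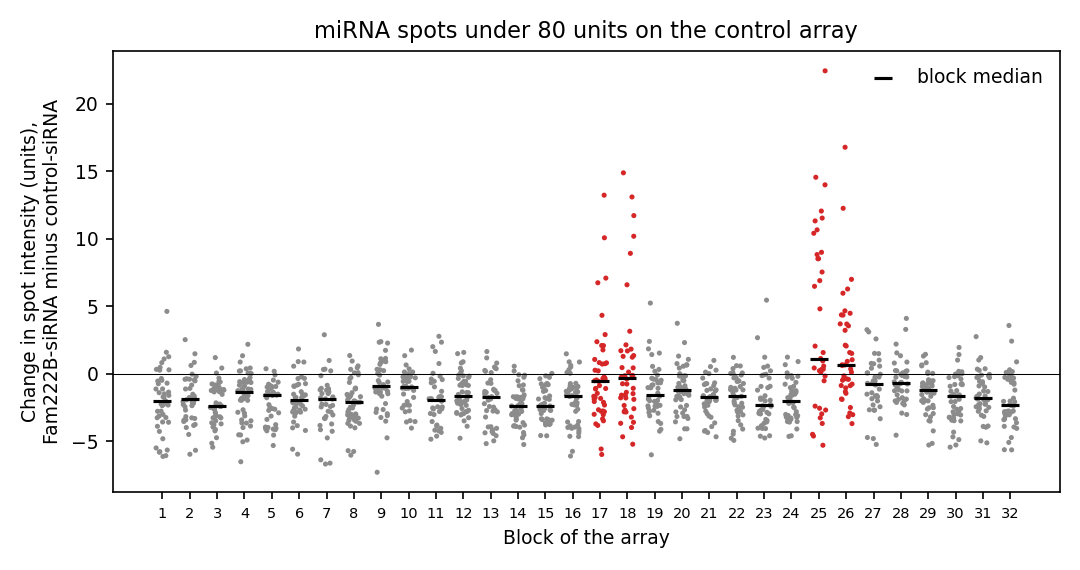
Change in spot intensity (Fam222B-siRNA minus control-siRNA, intensity units) of the miRNA spots under 80 units on the control array, by block of the array. Points are spots, jittered sideways, red in blocks 17, 18, 25 and 26, and black ticks are block medians; the red blocks were picked for holding at least 2 spots that gained over 5 units, and hold 30 of the 32 such spots.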

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

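Differences of the array's own control probes were not among the planned results, and the selection of those below was made after their values were seen. S-Probe26, S-Probe27, S-Probe28 and the 2 spike controls were the 5 probes behind the spot SDs. The spike controls also served for 1 added scaling. S-Probe1014, S-Probe1020 and S-Probe1021, control spots whose identity is not given in the sources used here, were higher on the Fam222B-siRNA array by more than 2 spot SD. With equal medians S-Probe1014 differed by 0.25 on the log2 scale, at 2189 net units against 1855. S-Probe1020 differed by 0.13, at 5.49 against 1.23 units. S-Probe1021, printed in block 25, differed by 0.21, at 16.8 against 8.44 units. On the same scale 6 control probes were lower by more than 2 spot SD: S-Probe26 (-0.19), Spike Control 2 (-0.17), Spike Control 1 (-0.14), S-Probe27 (-0.13), S-Probe28 (-0.12) and S-Probe1 (-0.050).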

How the results depend on the processing

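No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The alternatives that the methods list as added were chosen after seeing the data. Counts of 2-fold differences, 0 higher and 0 lower on the main scale, were also 0 and 0 under the planned scalings, filters, the offset of 16 and the 1.5-fold threshold. They were 38 and 12 with the blank mean subtracted and no offset, 26 and 22 in the authors' table, 27 and 22 with blank subtraction and equal medians (6 and 19 without the 4 blocks), 38 and 39 of 1089 with the No Probe background, and 5 and 14 with the BG_Median column. Removing the offset, by its construction, lets dim spots reach 2-fold. In simulated arrays with blank subtraction and equal medians 17 of 853 unchanged miRNAs did so. The authors' table is on nearly the same scale as blank subtraction with equal medians, so the 2 are not separate sources. The share of the 910 miRNAs with a higher value was 46.3% on the main scale, 63.2% with equal 75th percentiles and 98.5% with spike scaling, which moved the median of all by 0.15. These scalings shift all miRNAs alike, so a sign change under them says nothing of a miRNA or list relative to the others. Control-only detection was 161 at 5 SD and 170 with the No Probe background, and Fam222B-only detection was 104 with the No Probe background and 22 without the 4 blocks. Added later too, thresholds with the No Probe mean or SD alone gave 219 and 71, and 272 and 53. The correlation of hairpin arms was 0.073 at or above the median signal, 0.069 at 5 SD, 0.247 with the No Probe background, 0.081 without the 4 blocks and -0.061 with the BG_Median column. The p53-responsive median was -0.094 with offset 16, -0.14 with blank subtraction, -0.012 with equal 75th percentiles, -0.036 with the BG_Median column, 0.020 in the authors' table, 0.023 with blank subtraction and equal medians and 0.12 with spike scaling. Of the 26 named miRNAs past 2 spot SD, 11 changed sign with the BG_Median column, 4 with spike scaling and 0 under the other alternatives that gave them a value. With the BG_Median column these were miR-7053-3p (-0.0097), miR-211-5p (-0.69), miR-6919-3p (-0.00060), miR-6968-5p (0.23), miR-6955-5p (0.46), miR-34c-3p (0.065), miR-7000-3p (0.76), miR-5122 (0.14), miR-8113 (0.13), let-7k (-0.066) and miR-25-3p (-0.25). With spike scaling they were miR-6912-5p (0.0067), miR-10a-5p (0.048), miR-218-5p (0.0087) and miR-145a-5p (0.017). Except for the offset, the cause was not tested. Signal over background limits what can be read, since 746 of the 1219 detected miRNAs on the control-siRNA array had under 10 net units.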

Other observations

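The tests on detection, with the split of mean and SD, on copies of control probes and on single arms were chosen after the results were seen, while those on partner arms and on hairpins without the 4 blocks were written before. The explanation tested with partner arms was narrowed to hairpins with a partner outside the blocks after its value was known, with the test and its bounds kept.

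Control probes of strong signal differed between the arrays in both directions. Net signal of Spike Control 1 was 10.2% lower and that of Spike Control 2 12.2% lower on the Fam222B-siRNA array, and S-Probe27 and S-Probe28 were 11.6% and 9.14% lower, while S-Probe26 had a ratio of 0.860. S-Probe1014, at 2189 against 1855 net units, and S-Probe1018, at 1379 against 1303, were higher, with 1 spot each. The identity of the S-Probe spots is not given in the sources used here. Over the 96 miRNAs with at least 100 net units, such as let-7a-5p, miR-31-5p and miR-21a-5p, the median log2 ratio of unscaled net signals was 0.018, and it was 0.19 after scaling to the spikes.

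The miRNAs with the highest differences, miR-1971, miR-6394, miR-7053-3p and miR-211-5p among them, lie in 4 of the 32 blocks. The blocks were picked for dim miRNA spots that gained, miR-1971 and miR-7053-3p among them, so this placing is in part by construction. Control probes had no part in that choice. For 8 hairpins with the partner arm printed elsewhere, miR-211 and miR-25 among them, the partner's median difference was -0.0033 (SE 0.024 across hairpins). This value is on the main scale, which understates the change of dim arms. Arms outside the blocks also tracked each other weakly (r = 0.081). The partners therefore argue only weakly against a rise of whole hairpins in the cells. A local disturbance of the array surface or hybridisation may account for the grouping in blocks. Among control probes near background, copies of the same probe gained 2.73 units more inside the blocks than outside (SE 1.00, higher inside for 11 of 13 probes). Against a simple form of such a disturbance, 0 of 24 No Probe spots inside the blocks gained over 5 units, as did 0 of 150 outside. Their median change was -1.31 units inside and -1.09 outside, so spots without a probe showed no rise there. For 26 of the 34 miRNAs past 2 spot SD inside the blocks there was neither a measured partner nor a second probe elsewhere. For each of them, a rise of the single arm and a local disturbance cannot be told apart. For the block pattern as a whole, a rise in the cells would leave copies of control probes unmoved. Inside the blocks 3 of 19 copies gained over 5 units, against 0 of 141 outside, which argues against such a rise as the whole cause.

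The excess of miRNAs detected in control-siRNA cells alone, such as miR-672-3p and miR-669f-5p, was a ratio of 6.44 to those detected in Fam222B-siRNA cells alone, 3.74 with detection at 5 SD and 13.2 without the 4 blocks. With the No Probe spots setting the threshold it was 1.63. Their mean differed from the blank mean by -0.68 units on the Fam222B-siRNA array and by 0.090 on the control-siRNA array. A blank threshold set too high on the Fam222B-siRNA array would give such a fall. A lower threshold there also adds detections if weak miRNAs were lost, so the fall does not tell these apart. Use of the No Probe spots changes the mean and the SD together. With the mean alone changed the ratio was 3.08 and with the SD alone 5.13, so the mean level of the blank spots by itself is left open. A loss of weak miRNAs as the whole cause is argued against by the control probes near background, which changed by a mean of -1.05 net units over the 18 probes with at least 8 spots (SE 0.155 across probes, all 18 lower) and of -0.88 over all 31 (SE 0.389, 28 lower, and 3 higher including S-Probe1020 and S-Probe1021). A loss of some weak miRNAs in the Fam222B-siRNA cells stays open.

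The log2 differences of the arms of a hairpin correlated more than those of shuffled arms did, with r = 0.160. The share of arms with the same sign was not set against shuffled arms. The value was also lower among miRNAs at or above the median signal (0.073) and with detection at 5 SD (0.069), and -0.061 with the BG_Median column, but higher with the No Probe background (0.247), so it moves with settings other than the blocks. Without the 4 blocks r was 0.081, inside the shuffled range from -0.147 to 0.148. After blank subtraction with equal medians r went from 0.192 to 0.140 without the blocks, near the top of its shuffled range (-0.149 to 0.149). That drop is smaller than the bootstrap SD of r on the main scale (0.077), and the drop on the main scale is close to that SD. Arms printed side by side, as in 111 of the 220 hairpins, may share local errors. Leaving out the blocks removed hairpins with an arm there whether or not the arms were adjacent. Adjacent and other hairpins were not compared, so these values cannot decide on adjacent printing. A shared change of both products of a precursor stays open.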
